A study of Homo sapiens with 4 samples.

How the data were processed

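RNA of primary human melanocytes was measured on 4 Affymetrix Human Genome U133 Plus 2.0 arrays, 2 for cells given BRAFV600E lentivirus and 2 for cells given GFP lentivirus. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, biotin-labelled cRNA was made from 6 µg of total RNA by the array maker's standard method. The series' design text names RMA normalization with RMAExpress, and the submitters' processing notes name GCOS and RMA. Versions, RMA settings and scan batches are not given in the sources used here. The deposited values are RMA intensities on a linear scale, 1 per probe set, between 11.7 and 25632 on control replicate 1. RMA estimates a probe set's level after background correction and quantile normalization of probes, so a change in total signal per cell cannot be seen in it. The log2 of each deposited intensity was taken before testing, as the test had been planned for log2 values with this step if the values proved linear.

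The table held 54675 probe sets. The 62 control probe sets were left out of all tests and used only to describe the arrays. Of the other 54613, 41091 were paired with 1 gene symbol by the platform annotation, 1801 with several and 11721 are unnamed here. Gene identifiers of 41037 were found in the reference gene table of GRCh38.p14, used for names only, and 0 symbols changed. Probe sets with 1 symbol represented 19775 genes. Each gene was represented by its brightest probe set over the 4 arrays, and 4739 genes below the 40th percentile of all non-control probe sets, a log2 value of 4.64, were left out as dim. This left 15036 genes. Of the 78 genes given a difference of their own in the text, 38 had over 1 probe set above the limit, and in 8 of them (BCL2, CDK2, COL1A2, DUSP4, EGR1, INSIG1, KSR1 and PPARGC1A) the probe sets differed in sign.

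The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit on group means, eBayes without trend), 2-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The prior had 1.98 degrees of freedom. The 24 gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists, and again with an estimated correlation. The latter also rests on the few residual degrees of freedom of 4 arrays, so hardly any list could pass it. Failing it does not show that correlation among members accounts for a call. A directional p from limma's fry was planned beside camera and was not adjusted over the lists. Members were also adjusted over each list alone. The test, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule named the delivered gene, which is not analysed here, then up to 10 genes per direction that passed the threshold with both BRAFV600E arrays on one side of both controls. For each list it named up to 3 members per direction that passed, or otherwise the 2 members with the largest difference in size. Other genes named were chosen after their values were seen, including those that passed only when adjusted over a list alone. Lists of inflammatory cytokines and of matrix metalloproteinases were written with the study's known genes in mind.

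Alternatives covered the filter on dim genes, the choice among a gene's probe sets, normalization between arrays, the variance model, array weights, the replicate number as a block, leaving out each array, and the threshold. An intensity trend and robust variance do not enter camera, so list tests under them repeat the main run. The mean of a gene's probe sets was taken over those above the dim limit. With 1 array left in a group, that array was assumed to vary like the other group's arrays. Cyclic loess, cyclic loess or quantile normalization without BRAFV600E replicate 1, and a crossed block were added after seeing the data. Level-matched random lists, 10000 per list, were drawn for the closing section. The fit was tested on simulated data for BRAFV600E against control with 15036 genes, 200 of them changed, in 10 simulations. With the spread of each group as measured, limma recovered 7.6% of genes changed by a log2 difference of 1 and 69.2% at 2. At 4 and 6 it recovered 94.6% and 97.8%, and there were 9 false calls per simulation. The simulated noise was independent between genes and held no shift with signal level between arrays. These shares therefore need not hold for the measured arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Chromosomal positions are not used here, since no build of the array design was given.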

Results

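Gene expression was measured in primary human melanocytes, the pigment-producing cells of the skin, after lentiviral delivery of BRAFV600E, an activated form of a kinase of the ERK signalling cascade. Cells of 5 donors had been pooled and were used at passage 2. The virus was added at a multiplicity of infection of 10, with 6.0 µg/ml polybrene, and RNA was taken on day 5. Control cells received a lentivirus for GFP. There were 4 Affymetrix Human Genome U133 Plus 2.0 arrays, 2 per group, each hybridised with labelled RNA made from 6 µg of total RNA. The labels do not say that the replicates were separate cultures, so p-values measure only the spread between these arrays, which may be technical. Precision is limited by the number of arrays. The median RMA value over non-control probe sets was 31.4 and 28.7 on BRAFV600E replicates 1 and 2, against 27.8 and 27.9 on control replicates 1 and 2.

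The 4 arrays were not equally alike. Over the 15036 genes tested, the difference between the 2 control arrays had an SD of 0.18 on the log2 scale, and that between the 2 BRAFV600E arrays an SD of 0.67. The 90th percentile of RMA values was 161 on BRAFV600E replicate 1, 263 on replicate 2, and 319 and 307 on the controls. The 18 bacterial spike-in probe sets, which measure RNA added in the laboratory, lay above the control mean on both BRAFV600E arrays, by a median of 1.32 log2 units on replicate 1 and 0.59 on replicate 2. Genes with a control level between 8 and 9 had a median log2 difference from control of -0.94 on replicate 1 and -0.24 on replicate 2, whereas genes under 5 had medians of 0.33 and 0.12.

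**Figure D1:**
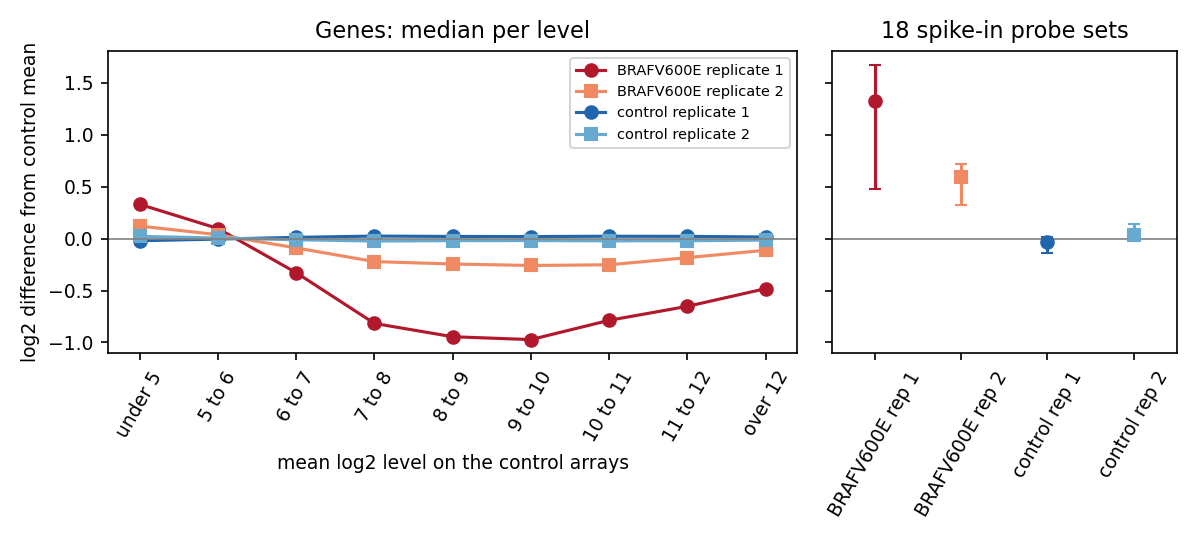
Log2 difference of each array from the mean of the 2 control arrays: at left the median over genes grouped by their mean log2 level on the control arrays, at right the 18 spike-in probe sets, with points for medians and bars from lowest to highest. BRAFV600E replicate 1 lies furthest from the controls, at -0.94 for genes of level 8 to 9 and 1.32 for the spike-in probe sets.

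The design asks which genes differ between melanocytes carrying BRAFV600E and melanocytes carrying the control virus. MMP1, an interstitial collagenase, rose from 4.09 ± 0.07 to 11.98 ± 0.40 on the log2 scale (mean ± SD, n = 2 arrays per group). Its log2 difference was 7.89 (SE 0.24, limma adjusted p = 0.0286). TFPI2, a secreted inhibitor of serine proteases, rose by 6.75 log2 units (SE 0.17, limma adjusted p = 0.0286). INHBA, which encodes the subunit of activin A, rose by 5.30 log2 units (SE 0.15, limma adjusted p = 0.0286). These were the 3 genes of 15036 that passed, all of them higher with BRAFV600E and all changed by at least 2-fold.

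The rises correspond to 237-fold for MMP1, 108-fold for TFPI2 and 39.3-fold for INHBA. All 3 genes lay below the limit used for dim genes, a log2 value of 4.64, on both control arrays. Set against that limit, their BRAFV600E means were 162-fold, 82.9-fold and 29.4-fold higher. A second TFPI2 probe set differed by 6.996 log2 units, while the other 2 INHBA probe sets differed by 0.54 and 0.11, the latter below the dim limit. No gene passed as lower (limma). At an unadjusted p under 0.05 there were 518 higher and 1652 lower genes, and the fourth-ranked gene had an adjusted p of 0.0734. Left-out arrays moved the count: limma called 2959 genes without BRAFV600E replicate 1, 9267 without BRAFV600E replicate 2, 0 without control replicate 1 and 0 without control replicate 2. The smallest p an exact permutation of 2 against 2 arrays allows is 0.333, so the calls rest on limma's shared estimate of the spread.

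**Figure D2:**
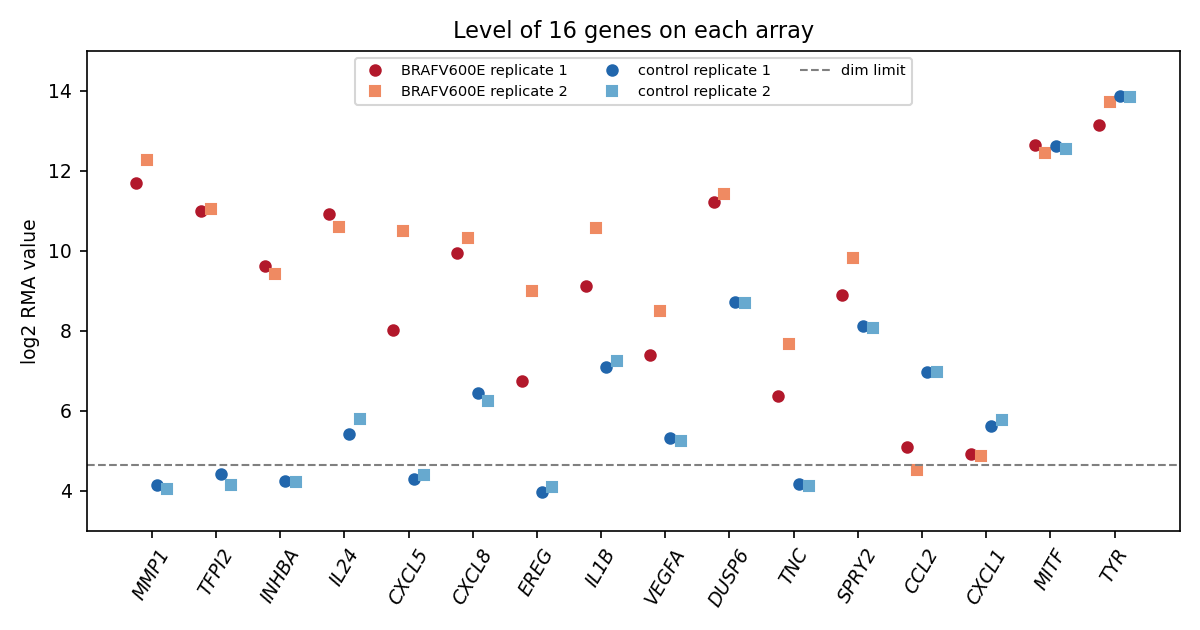
Log2 RMA value of 16 genes on each of the 4 arrays, 1 point per array, with the limit for dim genes as a dashed line. The BRAFV600E arrays lie at 11.70 and 12.27 for MMP1 and the control arrays at 4.14 and 4.04, whereas the 4 arrays lie close together for MITF.

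The BRAF gene itself was not analysed here, so the level of the delivered transcript gives no check of the labels. For the gene lists below, the counts of members that passed adjusted over a list alone depend on single arrays. Summed over the 24 lists they came to 24 as deposited, 125 without BRAFV600E replicate 1, 274 without BRAFV600E replicate 2, 4 without control replicate 1 and 5 without control replicate 2.

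Genes known as transcriptional output of ERK signalling were higher with BRAFV600E as a group by camera with a preset correlation (adjusted p = 3.14e-05). With an estimated correlation, a test with few degrees of freedom here, they did not pass camera (adjusted p = 0.739). Of 25 measured members, 19 had a positive and 6 a negative log2 difference, with a median of 0.52, which lies 0.61 above the median of all genes. The list median was 0.70 without BRAFV600E replicate 1 and 0.17 without replicate 2 (adjusted p = 0.0387). DUSP6, a phosphatase that inactivates ERK, differed by 2.62 log2 units (SE 0.15). The other DUSP6 probe sets differed by 2.55 and 0.90, the latter with BRAFV600E replicate 1 at 6.68, below both controls. The mean of the DUSP6 probe sets differed by 2.02. TNC, an extracellular matrix glycoprotein, differed by 2.87 (SE 0.49), with both TNC controls below the dim limit and a BRAFV600E mean 5.19-fold over it. None of the 25 passed over all genes tested, and 5 were higher when adjusted over the list alone: TNC, DUSP6, EGR1, IER3 and LIF. Over the list alone 17 passed without BRAFV600E replicate 1, 16 without replicate 2 and 0 without either control array. EGR1, an immediate early transcription factor, differed by 1.77 (0.91 as the mean of its probe sets), IER3 by 1.26 and the cytokine LIF by 1.11. SPRY2, a feedback inhibitor of receptor tyrosine kinase signalling chosen after its values were seen, differed by 1.27, by 0.81 on replicate 1 and 1.73 on replicate 2. DUSP4, also chosen after its values were seen, differed by -0.046, by -0.42 on replicate 1 and 0.33 on replicate 2.

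Inflammatory cytokines and chemokines moved in both directions, with the largest differences upward. This list is not an independent choice, since the study is known for members of it. Of 19 measured members none passed over all genes tested. Adjusted over the list alone, 7 were higher and 2 were lower, 9 in all, against 2 and 3 without control replicates 1 and 2, and 11 and 13 without BRAFV600E replicates 1 and 2. IL24, a cytokine of the IL-10 family, differed by 5.15 log2 units (SE 0.22, limma adjusted p = 0.0734). The neutrophil chemokine CXCL5 differed by 4.90 (SE 0.89), by 3.66 on replicate 1 and 6.14 on replicate 2. Both CXCL5 controls lay below the dim limit, and the BRAFV600E mean was 24.3-fold over it. The other CXCL5 probe sets, below the dim limit, differed by 0.63 and 0.029. The other higher members were CXCL8 at 3.79, IL1B at 2.67, CCL20 at 2.29, CXCL3 at 1.04, from controls below the dim limit, and IL1A at 0.96. A second CXCL8 probe set differed by 0.90, and the mean of the CXCL8 probe sets by 2.35. The lower members were CCL2, a monocyte chemokine, at -2.15 and CXCL1 at -0.81. The list was higher by camera with a preset correlation (adjusted p = 0.00298) and had an adjusted p of 0.68 with an estimated correlation.

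Growth factors and ligands were also higher as a group by camera with the preset correlation (adjusted p = 0.000243), but not with an estimated correlation (adjusted p = 0.68). Of 19 measured members 15 lay above 0, and the median was 0.33. The members are dim genes, with a mean level of 5.53, in a range where genes lay slightly higher on both BRAFV600E arrays. After cyclic loess the list median was 0.28 (camera adjusted p = 0.026). There the list lay at the 97.2 percentile of level-matched random lists on replicate 1 and the 99.58 percentile on replicate 2. INHBA was the 1 member past the threshold over all genes tested. Adjusted over the list alone, 2 members were higher, INHBA and VEGFA, the endothelial growth factor, at 2.66 (SE 0.41). The other 2 VEGFA probe sets above the dim limit differed by 0.14 and 0.19, and the mean over its probe sets by 0.998. EREG, a ligand of the epidermal growth factor receptor chosen after its values were seen, differed by 3.83 (SE 0.81), by 2.71 on replicate 1 and 4.95 on replicate 2. Both EREG controls lay below the dim limit, the BRAFV600E mean was 9.32-fold over it, and the mean of its probe sets differed by 2.03. In the list of matrix metalloproteinases, their inhibitors and plasminogen activation, also not an independent choice, MMP1 was the 1 of 17 measured members that passed, over all genes tested and adjusted over the list alone. That list had a median of 0.04 and did not pass camera as deposited (adjusted p = 0.0627), but was higher by camera in 10 of 18 other alternatives.

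The list of neural crest and undifferentiated melanoma genes was higher by camera (adjusted p = 0.0368). Its adjusted p was 0.68 with an estimated correlation. None of its 15 measured members passed over all genes tested, and 2 were higher adjusted over the list alone: TNC at 2.87 and NT5E, an ectonucleotidase, at 1.89 (SE 0.19). In the list of epithelial-mesenchymal transition, FN1, encoding fibronectin, at 1.81 (SE 0.18) and the integrin subunit ITGB3 at 0.99 (SE 0.14) were the 2 of 14 measured members that were higher adjusted over the list alone. The ITGB3 value comes from 1 probe set, the other 4 above the dim limit differing by 0.025 to 0.10, and ITGB3 differed by 0.26 as the mean of its probe sets. None passed over all genes tested, and the list did not pass camera (adjusted p = 0.142).

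Pigmentation and melanocyte lineage genes were among the brightest on the arrays, and none of the 25 measured members passed, over all genes tested or adjusted over the list alone. Without BRAFV600E replicate 2, 15 passed over the list alone. PMEL, a structural protein of melanosomes, differed by -1.68, but by -3.24 on replicate 1 and -0.12 on replicate 2. CDK2 differed by -1.56, by -2.82 on replicate 1 and -0.29 on replicate 2, and by -0.78 as the mean of its probe sets. Of the genes chosen after their values were seen, MITF, the lineage transcription factor, differed by -0.044 and TYR, which encodes tyrosinase, by -0.43 (-0.71 on replicate 1 and -0.15 on replicate 2). A second MITF probe set differed by -1.50, with both BRAFV600E arrays below both controls, and a second TYR probe set by -3.03, at 5.56 on replicate 1 and 10.89 on replicate 2. As the mean of its probe sets MITF differed by -0.77 and TYR by -1.73. The list median was -0.34 and camera's adjusted p was 0.142. The list was lower by camera in 3 of 18 other alternatives, and its median was 0.013 after cyclic loess.

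Among 48 measured cell division genes none passed, over all genes tested or adjusted over the list alone, and camera's adjusted p was 0.744. Over the list alone 16 passed without BRAFV600E replicate 1, 24 without replicate 2 and 4 after cyclic loess. KIF23, a motor protein of cytokinesis, differed by -2.17 (SE 0.59) and RRM2, a subunit of ribonucleotide reductase, by -1.77 (SE 0.51). KIF23 was at -2.97 on replicate 1 and -1.36 on replicate 2, and RRM2 at -2.45 and -1.08. AURKA and CCNB1, mitotic regulators chosen after their values were seen, differed by 1.30 and 0.81, AURKA by 0.81 as the mean of its probe sets and CCNB1 by 0.43 on replicate 1 and 1.19 on replicate 2. None of 16 CDK inhibitor and senescence genes passed either test (camera adjusted p = 0.142). In that list CDKN1C differed by -1.43, by -2.44 on replicate 1 and -0.42 on replicate 2, and by -0.38 as the mean of its probe sets. CDKN2B differed by 1.17, by 0.19 on replicate 1 and 2.16 on replicate 2, from controls below the dim limit. CDKN1A and CDKN2A, chosen after their values were seen, differed by -0.43 (-0.92 on replicate 1 and 0.066 on replicate 2) and 0.26. None of 17 p53 targets passed either test (camera adjusted p = 0.0627), with SESN1 at -1.79 and PLK2 at -1.35. SESN1 was at -2.57 on replicate 1 and -1.01 on replicate 2, and PLK2 at -2.42 and -0.28.

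Mitochondrial respiration genes were lower as a group, with 21 of 25 measured members below 0 and a median of -0.54, by camera with the preset correlation (adjusted p = 0.0276). The adjusted p was 0.869 with an estimated correlation. TFAM, a mitochondrial transcription factor, differed by -1.35 (SE 0.52), by -2.03 on replicate 1 and -0.67 on replicate 2, and by -0.066 without _x_at probe sets. PPARGC1A, a coactivator of mitochondrial biogenesis, at -1.14 (SE 0.14), was the 1 member lower adjusted over the list alone, and none passed over all genes tested. As the mean of its probe sets PPARGC1A differed by -0.45. The members are bright genes, with a mean level of 9.57, in the range where BRAFV600E replicate 1 lay furthest below the controls. Without that array the list no longer passed (adjusted p = 0.0602, median -0.23).

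The other lists of signalling and metabolism did not pass camera as deposited, and none of their members passed over all genes tested. Adjusted over the list alone, 1 of 17 genes of ER stress and ATF4 was higher, the cystine transporter SLC7A11 at 2.24 (SE 0.31, 1.39 as the mean of its probe sets; camera adjusted p = 0.679). HSPA5 differed by -1.12, by -2.27 on replicate 1 and 0.035 on replicate 2. No member passed over the list alone in the following lists, and pairs in brackets are the differences on BRAFV600E replicates 1 and 2. In 12 components of the RAF-MEK-ERK cascade, RPS6KA3 differed by -1.34 (-2.15 and -0.54) and KSR1 by -0.83 (-1.35 and -0.31), with a camera adjusted p of 0.404. In 12 AP-1 family genes, MAF differed by -1.12 (-1.96 and -0.28) and MAFF by 0.69, with an adjusted p of 0.404. After cyclic loess MAF was at -0.62 and MAFF at 1.21. In 22 glycolysis genes, ENO2 differed by -1.26 (-2.01 and -0.52) and PFKM by -1.21 (-1.97 and -0.46), with an adjusted p of 0.85. In 13 cholesterol synthesis genes, INSIG1 differed by 0.60 (0.044 as the mean of its probe sets) and MSMO1 by 0.56 (adjusted p = 0.699). After cyclic loess INSIG1 was at 1.10 and MSMO1 at 1.06. That list was higher by camera in 5 of 18 other alternatives, among them quantile normalization again (adjusted p = 0.0166, median 0.24). In 19 lysosome genes, CTSK differed by -1.53 (-2.70 and -0.36) and ATP6V1B2 by -1.39 (-2.61 and -0.16), with an adjusted p of 0.288. In 15 apoptosis regulators, PMAIP1 differed by 1.06 (0.69 and 1.42) and BCL2 by -0.89 (-1.50 and -0.28), with an adjusted p of 0.404 and the PMAIP1 controls below the dim limit. As the mean of their probe sets, KSR1 was at -0.063, MAF at -0.47, BCL2 at -0.20 and HSPA5 at -0.74. Camera ranks a list against all other genes. It gave an upward direction for ER stress and ATF4, cholesterol synthesis and apoptosis regulators, whose medians were -0.23, -0.10 and -0.09 and whose means were -0.08, -0.08 and -0.02.

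Of the immune lists, 21 interferon response genes (camera adjusted p = 0.744) and 17 antigen presentation genes (adjusted p = 0.404) held no member that passed either test. IFIH1, a sensor of viral RNA, differed by -1.76 (SE 0.37) and IFIT5 by -1.62, by -2.54 on replicate 1 and -0.70 on replicate 2. CD74 differed by 1.03 (1.42 and 0.65) and HLA-B by -0.97 (-1.79 and -0.15), and as the mean of their probe sets by 0.51 and -0.44.

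Markers of other skin cell types differed in both directions. The fibroblast list was higher by camera (adjusted p = 0.0448), with a median of 0.32 over 13 measured members. Its members are dim, with a mean level of 5.68, and after cyclic loess the list did not pass camera (adjusted p = 0.377, median 0.24). Its adjusted p was 0.68 with an estimated correlation, 0.0916 without BRAFV600E replicate 1 (median 0.18) and 0.139 without _x_at probe sets (median 0.15). No fibroblast marker passed over all genes tested or adjusted over the list alone, and the largest differences were those of FAP at -1.53 (-2.16 on replicate 1 and -0.89 on replicate 2) and COL1A2 at -0.86 (-1.31 and -0.41; -0.37 as the mean of its probe sets). None of 12 keratinocyte markers passed either test (camera adjusted p = 0.167), with CDH3 at -1.07 (-1.98 and -0.16) and LAMB3 at 0.70 (1.04 and 0.35), from controls below the dim limit. None of 7 leukocyte and Langerhans cell markers passed either test (camera adjusted p = 0.0627), with CD74 at 1.03 and HLA-DRA at 0.61. Of 5 endothelial markers, EMCN was lower adjusted over the list alone at -1.12 (-0.69 after cyclic loess). PECAM1 differed by 0.38 (0.59 and 0.17, and 0.78 as the mean of its probe sets). None of the 5 passed over all genes tested (camera adjusted p = 0.744).

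Of the 24 lists, 6 passed camera with the preset correlation, 5 higher and 1 lower. With an estimated correlation 0 passed, the lowest adjusted p being 0.68. Neural crest genes and fibroblast markers had that value too, with estimated correlations of -0.0022 and -0.072. Both lie below the preset 0.01, so for these lists the few degrees of freedom, not correlation, limit the test. The calls for ERK pathway output, inflammatory cytokines and growth factors held in all 18 other alternatives, and those for neural crest genes, mitochondrial respiration and fibroblast markers ended in 5, 8 and 11 of them. In those alternatives the medians ran from 0.17 to 0.93, 0.073 to 0.61, 0.20 to 0.40, 0.12 to 0.29, -0.83 to 0.0086 and 0.069 to 0.34 in that order. An intensity trend and robust variance, counted among the 18, do not enter camera and only repeat its result as deposited. The unadjusted directional p of limma's fry for the 6 called lists was 0.0728, 0.0115, 0.00402, 0.0620, 0.146 and 0.0152 in the same order. Of the lists not called, leukocyte markers (0.00249) and keratinocyte markers (0.0429) also lay under 0.05 by fry. Of the 18 lists that did not pass camera as deposited, 11 passed camera in some other alternative, including ones chosen after seeing the data. Higher were metalloproteinases in 10, cholesterol synthesis in 5, leukocyte markers in 4, CDK inhibitors in 3, epithelial-mesenchymal transition, ER stress and glycolysis in 2 each and apoptosis regulators in 1. Lower were p53 targets in 4, pigmentation in 3 and lysosome in 1. Glycolysis had a median of -0.32 as deposited, and its calls came without BRAFV600E replicate 1, at 0.27 with cyclic loess (adjusted p = 0.00346).

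**Figure D3:**
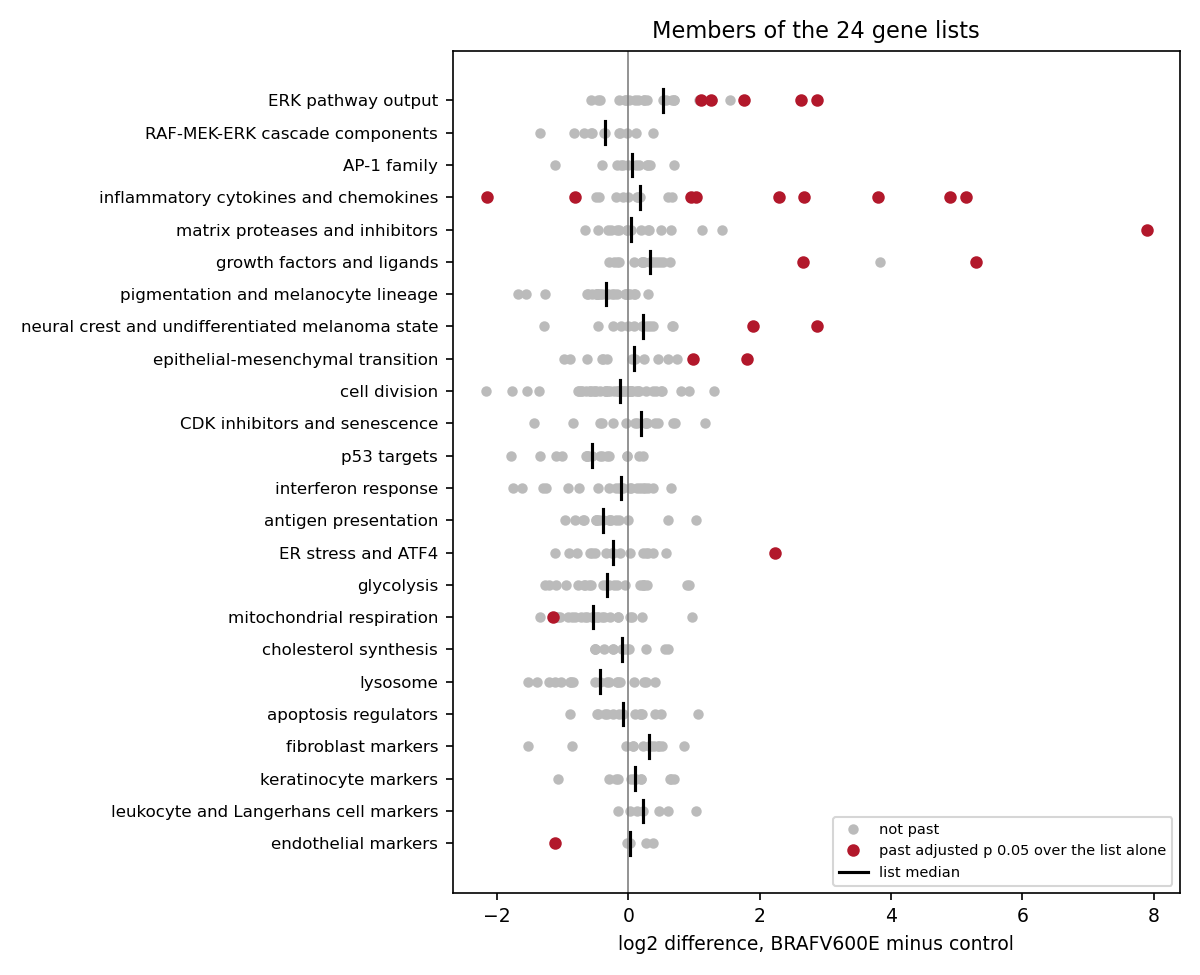
Log2 difference, BRAFV600E minus control, of every measured member of the 24 gene lists, 1 point per gene, with a vertical bar at each list's median. Red points passed an adjusted p of 0.05 over their list alone, among them MMP1 at 7.89, INHBA at 5.30, IL24 at 5.15 and CCL2 at -2.15.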

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

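The tests of spike-in signal, RNA degradation, array similarity, the fall on replicate 2, fibroblast markers and keratinocyte markers, and the test of MMP1, TFPI2 and INHBA against the intensity shift, were chosen only after the result was seen; those on the 2 gene lists were set before.

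The bacterial spike-in probe sets, which the comparison does not use, stood above the control arrays by a median of 1.32 log2 units on BRAFV600E replicate 1 and 0.589 on replicate 2, with all 18 raised on both arrays. A candidate explanation is weaker signal from the sample RNA against a fixed amount of spike-in. It stays open, since the rise of 1.32 is the observation that prompted it and no separate value tests it. RNA degradation on replicate 1 stays open. Of 4 ratios of 3' to 5' or middle probe sets of ACTB and GAPDH, 2 were highest there. ACTB 3' to middle was clearly highest, at 23.99 against 8.81 to 11.49 on the other arrays. GAPDH 3' to middle was highest by little (9.15 against at most 8.87). The ACTB 3' to 5' ratio was the lowest of the 4 arrays (42.6 against 71.9 to 90.9). On all 4 arrays, controls included, 3' signal far exceeded 5' signal, with GAPDH 3' to 5' ratios from 22.1 to 44.8. How far this affects the values of single genes and probe sets was not tested. For the excess fall of bright genes on replicate 1 the cause stays open. In genes of control level 8 to 9 the BRAFV600E arrays differed 17.3 times as much as the control arrays, but this restates the excess fall and tests no cause of it. For the smaller fall on replicate 2, -0.245, the raised spike-in signal and an effect of BRAFV600E cannot be told apart, because both occur on the same array.

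The rise of MMP1, TFPI2 and INHBA is argued not to come from the intensity shift, since it far exceeds that shift. Genes of control level under 5 had median differences of 0.33 on replicate 1 and 0.12 on replicate 2. The filter on dim genes raises these medians in part. At control level 5 to 6 the medians were 0.097 and 0.037. After cyclic loess the smallest difference of the 3 genes on either BRAFV600E array was 5.38. Removing so small a shift could not have undone the rise, so that value adds no test. Fibroblasts among the BRAFV600E cells, as the main source, are argued against: COL3A1, LUM, DCN and COL6A3, abundant in fibroblasts, had a median difference of 0.264 after cyclic loess, where a rise above 2 was called for. For keratinocytes only 2 markers were used, KRT5 at -0.28 and KRT14 at 0.50 after cyclic loess (median 0.109), which went opposite ways. Neither reached the rise above 2 that was called for, which argues against keratinocytes as the main source only. KRT10 was left out after its values were seen, because its high baseline would hide a small share. A small share of keratinocytes stays open. A response to BRAFV600E may account for the rise, as a hypothesis, with variation between cultures of 1 donor pool untested.

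The lower mitochondrial respiration list may come from the intensity shift. After cyclic loess its median on replicate 2 lay at the 13.21 percentile of level-matched random lists, and at the 4.44 percentile on replicate 1, inside the middle 95 percent on both. The ERK pathway output list lay at the 99.55 percentile on replicate 1 and the 100 percentile on replicate 2, as higher ERK output would give. The random lists were drawn gene by gene, so they leave out the correlation among members, estimated at 0.264 for this list. With an estimated correlation camera's adjusted p for the ERK list was 0.739. With the few residual degrees of freedom of 4 arrays, that p cannot tell whether correlation accounts for the call. The list's genes answer to other signals too, and kinase activity was not measured. The ERK list was not alone. In the top 2.5 percent lay 2 of 24 lists on replicate 1, the other being CDK inhibitors and senescence at 97.65, which reached 99.83 on replicate 2. On replicate 2, 10 of 24 lists lay there, among them inflammatory cytokines (100), glycolysis (99.97), growth factors (99.58), ER stress (99.47) and cholesterol synthesis (99.32), so that array separates the lists little.

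When all 32768 probe sets above the dim limit were tested with limma, 2 probe sets without a single gene symbol here passed, with log2 differences of 7.16 and 7.86 (adjusted p = 0.0343 for both).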

How the results depend on the processing

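The 3 calls, MMP1, TFPI2 and INHBA, kept their direction in all 18 alternatives that give a gene's value, with log2 differences of 7.61 to 8.40, 6.61 to 7.23 and 2.92 to 5.69. They passed in 15, 15 and 14 of them, and adjusted p ranged up to 0.902. The lowest INHBA value is the mean of its probe sets above the dim limit. Direction and size could not differ under an intensity trend, robust variance, array weights or the replicate block. These leave a log2 difference here as it is. The count of genes past the threshold, all higher and all at least 2-fold, was 6 with the mean of a gene's probe sets, 5 with an intensity trend, 10 with array weights and 0 at an adjusted p of 0.01. With all probe sets tested 5 probe sets passed, 3 of them with 1 gene symbol and 2 without. With quantile normalization again it was 3, of which 2 were among the 3 genes: INHBA had an adjusted p of 0.0721 and CXCL8 passed. Same-numbered arrays had deviations from their group means correlated at -0.25 across genes. The labels do not say whether the replicate numbers pair the arrays. This correlation cannot decide it, since the deviations also follow signal level. The replicate block left 0 genes past limma's threshold, of any size, with 1198 at an unadjusted p under 0.05, and the crossed replicate block 0, with 2273. Leaving out 1 array gave counts from 0 to 9267, and from 0 to 3518 changed at least 2-fold. Without a control array the spread rests on the unlike BRAFV600E pair. Without BRAFV600E replicate 1 the counts were 2959 (721 higher, 2238 lower) and 270, and without replicate 2 they were 9267 (3149 higher, 6118 lower) and 3518, with the spread taken from the control pair. Chosen after seeing the data, cyclic loess gave 16 genes, all higher and at least 2-fold, among them DUSP6, IL24, CXCL8, CCL20 and SLC7A11. Without BRAFV600E replicate 1, it gave 1339 (634 higher, 705 lower), 176 of them at least 2-fold, and quantile normalization again gave 1285 (660 higher, 625 lower), 189 of them at least 2-fold. Gene lists past camera numbered 3 without _x_at probe sets, 0 with an estimated correlation and 11 with cyclic loess without BRAFV600E replicate 1. The median difference of all genes was -0.09 as deposited, 0.06 after quantile normalization, -0.20 with arrays centred and 0.03 after cyclic loess.

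Of the 78 genes given a difference of their own, 8 changed sign in some alternative, and the cause was not tested. DUSP4 was at 0.20 with the mean of probe sets, 0.54 with quantile normalization and 0.44 with cyclic loess. Quantile normalization and cyclic loess gave 0.31 and 0.35 for MITF and 0.19 and 0.085 for CDKN1A. The mean of probe sets gave -0.77 for MITF, so its alternatives run from -0.77 to 0.35. Leaving out 1 array gave ranges of -0.42 to 0.33 for DUSP4, -0.14 to 0.057 for MITF, -0.92 to 0.066 for CDKN1A and -2.27 to 0.035 for HSPA5. Without BRAFV600E replicate 1, cyclic loess and quantile normalization gave 0.11 and 0.066 for PMEL, 0.10 and 0.075 for HLA-B, 0.28 and 0.25 for HSPA5, 0.074 and 0.033 for ATP6V1B2, 0.099 and 0.075 for CDH3, 0.57 and 0.58 for DUSP4, and 0.32 and 0.31 for CDKN1A. MITF was at 0.046 with cyclic loess there. Signal near the dim limit bounds how far low control levels, such as those of MMP1, can be measured.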

Other observations

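Several genes outside the lists, chosen after their values were seen, lay at least 2-fold higher on both BRAFV600E arrays than on both control arrays. BEX1 differed by 4.50 log2 units (SE 0.26), TMEFF2, a transmembrane protein with follistatin-like domains, by 4.27 (SE 0.36), the long noncoding RNA LINC00973 by 4.02 (SE 0.19) and SCG5, a neuroendocrine chaperone, by 3.51 (SE 0.16). Both control arrays lay below the dim limit for LINC00973 and SCG5, so these differences are measured from a background level. Over that limit itself the BRAFV600E means were 10.4-fold and 9.06-fold. SCG5 had a limma adjusted p of 0.0734 as deposited and 0.00857 after cyclic loess. Over its alternatives that p ranged from 8.20e-11 to 0.902. GPAT3, an enzyme of glycerolipid synthesis, differed by 3.63, the Wnt antagonist DKK1 by 2.93 and the decoy receptor IL13RA2 by 2.85. The control means of GPAT3 and IL13RA2, 4.61 and 4.54, lay below the dim limit, and their BRAFV600E means were 12.1-fold and 6.68-fold over it. PHLDA2 differed by 2.68 (1.43 as the mean of its probe sets), the phosphate transporter SLC20A1 by 2.43 and ANXA1, a phospholipid-binding protein, by 2.20. The metallothioneins MT2A, MT1X and MT1H, which bind zinc and other metals, differed by 1.96, 1.78 and 1.46, with MT1H short of the 2-fold margin on replicate 1. Their probe sets can share sequence within the family. None of these genes passed over all genes tested in limma as deposited. After cyclic loess, chosen after seeing the data, BEX1, LINC00973, SCG5, PHLDA2, SLC20A1, ANXA1 and MT2A passed, with adjusted p from 0.00857 to 0.0449.

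In all, 44 genes were at least 2-fold higher and 108 at least 2-fold lower on both BRAFV600E arrays than on both controls. After cyclic loess the numbers were 72 and 37, and 43 and 37 genes were on both lists. Without a size limit, 3809 genes had both BRAFV600E arrays above both controls and 6049 below. Chance places 33.3% of genes in one or the other only if all arrays are interchangeable, which they were not. The difference between arrays had an SD of 0.18 in the control pair and 0.67 in the BRAFV600E pair. Bright genes also lay lower on both BRAFV600E arrays, and dim genes higher, the latter in part through the filter on dim genes. The counts of 3809 and 6049 therefore cannot be judged against that share, and no effect of BRAFV600E is read from them.

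The BRAFV600E arrays differed in some lists after cyclic loess. The glycolysis list had a median difference of -0.18 on replicate 1 and 0.24 on replicate 2, antigen presentation -0.37 and 0.18, and lysosome -0.51 and -0.06. These differences between 2 arrays were not tested.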
